A study of Mus musculus with 6 samples.

How the data were processed

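The samples were burst-forming unit erythroid cells (BFU-E), early progenitors of red blood cells, from livers of mouse embryos (129/SvImJ) at embryonic day 14.5. Per the labels, cells were depleted of lineage markers, Sca-1, CD16/32, CD41 and CD34, kept for c-kit and sorted for the 10% lowest in CD71. The serum-free medium held 100 ng/mL stem cell factor, 40 ng/mL insulin-like growth factor 1 and 2 U/mL erythropoietin. The 3 groups were untreated cells, cells with 100 nM dexamethasone, and cells with 100 nM dexamethasone and 10 µM GW7647, with 2 libraries each. Dexamethasone is a synthetic agonist of the glucocorticoid receptor, and GW7647 is an agonist of the nuclear receptor PPARα. The labels give a treatment of 12 h, while the column headers of 1 of the 2 deposited tables carry 36 h, and the deposited values do not show which holds. The labels also leave open whether untreated cells were cultured or taken fresh. No group had GW7647 alone, so a joint effect of both drugs beyond the sum of their separate effects could not be tested. RNA was extracted with TRIzol and made into polyA-selected TruSeq libraries.

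Per the labels, the authors processed the reads with TopHat 1.4.1, HTSeq and DESeq, and the notes name the genome builds mm9 and NCBIM37. Whether HTSeq counted by strand is not stated, so counts of overlapping antisense genes are uncertain, as are counts shared between near-identical genes such as Hba-a1 and Hba-a2 or Acot1 and Acot2. The 2 deposited tables hold 37620 Ensembl genes each, with whole-number read counts per library. The deposited normalized signal is each count divided by 1 size factor per library, set by the authors separately in each table. The tables also hold the authors' fold ratio of group means, and the authors' p_value per gene with its adjusted form. The counts of the libraries with both drugs were identical in both tables. The deposited log2 column held text where a group was at 0 and was not used. Symbols were joined by Ensembl identifier from a later annotation, GRCm38 release M21, and were found for 32897 genes (87.45%). The annotation of build NCBIM37 was not available, so no gene positions are given.

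The counts of all 6 libraries were analysed with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr with a minimum count of 10 were kept, which left 14125 genes, 13577 of them with a symbol, holding 99.971% of the counts. Libraries were scaled by trimmed mean of M values (TMM), and each comparison used the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Both deposited pairs and dexamethasone against untreated were tested, and the log2 differences are written as the group named ahead minus the group named after it. The plan had named the limma-trend test for dexamethasone against untreated and the authors' p for the gene lists. Since counts were given for every library, edgeR served for all of these, and limma-trend and the authors' p are alternatives. Normalized counts in the text are counts divided by the TMM-scaled library size and multiplied by the mean of those sizes, given as mean ± SD over the 2 libraries of a group, and log2 differences are given ± SE.

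The 23 gene lists and the choice of named genes were fixed before the data were examined. The lists cover glucocorticoid receptor targets, PPAR targets in fatty acid metabolism, nuclear receptors and coregulators, erythroid differentiation, heme synthesis and iron, early progenitor genes, the cell cycle, cell cycle inhibitors, cholesterol and lipid synthesis, LXR targets, inflammatory and interferon genes, cytokine signalling and immediate early genes, apoptosis, the stress response, hypoxia and glycolysis, and ribosome biogenesis with MYC targets. A further 7 hold markers of megakaryocytes, mast cells and basophils, granulocytes and eosinophils, monocytes and macrophages, lymphoid cells, hepatoblasts, and endothelial and stromal cells. Genes named for each comparison were the 8 largest rises and the 8 largest falls among called genes with a mean of at least 50 normalized counts, up to 4 members with the smallest p from each list with a called member, and always Nr3c1, Ppara, Kit, Gata1, Fkbp5, Tsc22d3, Zfp36l2, Cpt1a, Pdk4 and Angptl4. Some of these genes are not reported here. A list member counted as measured with a mean of at least 10 normalized counts in the comparison. Lists were tested with cameraPR of limma 3.58.1 on the signed edgeR scores, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. With the correlation estimated from these libraries instead (camera), 0 of the 23 lists passed in any of the 3 comparisons. The p from that test is given beside each called list. The test takes its degrees of freedom from the 6 libraries less the 3 groups, so it has little power here. Correlation alone does not set its larger p, since some estimates lay below the preset 0.01. The estimate for mast cell and basophil markers with GW7647 added to dexamethasone was -0.106. The median of each list was also set among 10000 random lists matched on mean expression and called outside their central 95%.

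Totals ranged from 35970286 to 54174801 counts per library. For a group with 1 to 3 counts of a gene, the ratio of counts is given with its 95% counting interval, and a group with 0 counts is set at a floor of 3 counts over the group. These intervals and floors cover counting error only, since the reads carried no molecular identifiers. On simulated counts of the same depth and spread, 200 of the 14125 genes were changed for each comparison. The edgeR test recovered 72% to 88% of genes changed 2-fold and 96% to 100% of genes changed 4-fold. Of its calls, 8.16% to 13.2% were genes left unchanged. Far more genes were called in the data, and these rates depend on the share of genes changed, so they need not hold there. Libraries with the same replicate number were not treated as pairs, because the labels give them no shared source. The labels do not say whether the 2 libraries of a group came from separate animals or cultures, so the p values measure only the spread between these libraries, which may be technical.

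Alternatives covered other thresholds, DESeq2 1.42.0, limma-trend and voom, DESeq2 size factors, total count scaling, other filters, the authors' deposited p values, a block for replicate number, and leaving out each library in turn. Those chosen after seeing the data were edgeR with total count scaling, with genes of any count, with robust dispersions and on the 4 libraries compared, a crossed block of replicate numbers, libraries thinned to the smallest total, the list tests under each other fit, and the overlap of calls under DESeq2 and under total count scaling. With a library left out, its group's remaining library is assumed to vary like the other groups.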

Results

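Gene expression was measured by RNA sequencing in 6 libraries of fetal liver BFU-E, 2 from untreated cells, 2 from cells with dexamethasone (Dex) and 2 from cells with Dex plus GW7647. The untreated libraries held 37577414 and 39791302 counts, the Dex libraries 54174801 and 45058773, and the libraries with both drugs 46716806 and 35970286. Pearson correlations across genes between the libraries of a group were 0.996, 0.996 and 0.996 for untreated, Dex and Dex plus GW7647, and genes are not independent replicates. Chi-square per degree of freedom between those libraries was 8.25, 20.5 and 3.75, a measure that also grows with depth, so the pairs were not equally close. In a principal component analysis, the component with 75.1% of the variance set untreated apart from treated libraries, and the next, with 12.4%, set Dex apart from Dex plus GW7647. Transcripts of globin genes took 6.48% and 7.15% of the counts in untreated libraries, 3.12% and 2.96% after Dex, and 2.82% and 2.76% after both drugs. Mitochondrial transcripts took 1.73% of counts in Dex replicate 1 and between 2.46% and 2.88% in the other 5 libraries. All means below are over 2 libraries (n = 2, SD).

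With Dex against untreated, 14 of 23 measured glucocorticoid receptor targets were higher and 5 lower, and 20 of 34 erythroid differentiation genes were lower and 7 higher. The receptor list was called higher (adjusted p = 0.00608, and adjusted p = 0.319 with an estimated correlation) and the erythroid list lower (adjusted p = 0.000929, and adjusted p = 0.28 with an estimated correlation). Mt2, a metal-binding metallothionein and receptor target, rose from 231.7 ± 33.7 to 10200 ± 187 normalized counts, a 43.9-fold difference (log2 5.46 ± 0.09, adjusted p = 8.74e-10). Fkbp5, which encodes a co-chaperone of the receptor, rose 3.06-fold, from 1742 ± 38.1 to 5331 ± 81.2 (adjusted p = 6.36e-09). Kit, the receptor for stem cell factor, rose 2.95-fold, from 4291 ± 28.6 to 12660 ± 36.9. Slc4a1, the anion exchanger of the red cell membrane, fell from 159600 ± 3590 to 58900 ± 836 normalized counts (log2 -1.44 ± 0.04, adjusted p = 8.08e-09).

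The comparison asks which genes respond to glucocorticoid in these progenitors. Of the 14125 genes tested with edgeR, 7283 (51.6%) were called, 3606 higher and 3677 lower after Dex, and 729 and 989 of these differed at least 2-fold. Scaling by total counts, chosen after seeing the data, raised the median difference of all genes by 0.13 on the log2 scale and gave 8035 calls, 5451 higher and 2584 lower, so the balance of directions rests on the scaling.

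Of the 23 measured glucocorticoid receptor targets, 4 were not called, and the counts adjusted over the list alone were 14 higher and 5 lower. Ddit4, an inhibitor of the growth kinase mTORC1, rose 3.35-fold to 3326 ± 12.9 normalized counts. Zfp36l2, an RNA-binding protein that promotes mRNA decay, rose 2.37-fold, from 9227 ± 218 to 21860 ± 489. Tsc22d3, a leucine zipper protein also known as GILZ, rose 2.53-fold, from 740.4 ± 30.5 to 1876 ± 46.4. Nr3c1, which encodes the receptor, stood at 2775 ± 11.8 and 2569 ± 157 normalized counts (log2 -0.11 ± 0.05, adjusted p = 0.112), and it was called lower when Dex replicate 2 was left out (adjusted p = 0.0142).

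Of the 34 measured erythroid differentiation genes, 7 were not called, and 8 were higher and 20 lower adjusted over the list alone. With total count scaling, 8 were higher and 16 lower, and the list median went from -0.224 to -0.094 on the log2 scale. Besides Slc4a1, Hemgn, an erythroid nuclear protein, fell from 15790 ± 233 to 5230 ± 303 normalized counts, and Trim10, a gene needed for terminal red cell development, fell by 1.04 on the log2 scale. Against this direction, Hbb-y, an embryonic beta-like globin, rose 17.9-fold, from 40.85 ± 7.64 to 734.6 ± 58.9. The adult globin genes, which the naming rule does not take in and which were chosen after their values were seen, also fell. Hba-a1 went from 435100 ± 56600 to 175900 ± 9740 normalized counts, Hba-a2 from 330500 ± 54400 to 116500 ± 10800, and the log2 differences were -1.17 ± 0.04 for Hbb-bs and -1.39 ± 0.08 for Hbb-bt. Gata1, the main transcription factor of the lineage, fell by 0.19 (adjusted p = 0.01), a call lost without untreated replicate 2 (adjusted p = 0.0871) and under total count scaling (adjusted p = 0.331).

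Heme synthesis and iron genes followed the same direction, with 1 of 20 measured members higher, 15 lower and 4 not called, and 1 and 15 adjusted over the list alone (adjusted p = 0.000177, and adjusted p = 0.284 with an estimated correlation). Alas2, the erythroid enzyme that begins heme synthesis, fell from 73750 ± 393 to 39240 ± 1170 normalized counts. Slc25a37, the mitochondrial iron importer, fell by 0.84 on the log2 scale, and Hmox1, the heme-degrading oxygenase, fell from 11510 ± 669 to 2717 ± 133. The counts were 4 higher and 12 lower under total count scaling.

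Early progenitor genes went both ways: of 23 measured, 5 were higher, 11 lower and 7 not called (7 and 11 adjusted over the list alone), and the list was not called (adjusted p = 0.209). Scaled by total counts, 10 were higher and 11 lower. While Kit rose, Meis1, a homeobox factor of stem and early progenitor cells, fell by 1.42 on the log2 scale, and Lmo2, a cofactor of Tal1, fell from 19580 ± 466 to 11980 ± 87.1 normalized counts. Cell cycle genes were lower for 25 of 32 measured members and higher for 0, with 25 lower adjusted over the list alone (adjusted p = 2.19e-06, and adjusted p = 0.13 with an estimated correlation). Ccne1, cyclin E1 of the entry into S phase, fell from 6659 ± 105 to 3731 ± 33.9 normalized counts, and Mki67, a marker of cycling cells, fell from 71570 ± 5490 to 48190 ± 3250. Under total count scaling, 16 cell cycle members were lower and 1 was higher. Of 16 cell cycle inhibitors, 8 were higher and 8 lower, adjusted over the list alone as well (adjusted p = 0.642, a test pointing down beside a median of 0.01 and a mean of 0.02). Ccng1, a p53 target, rose 2.00-fold, and Gadd45a, a growth arrest gene, fell from 39270 ± 792 to 11370 ± 47.3.

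Of 31 measured genes of cholesterol and lipid synthesis, 23 were lower and 3 higher (25 and 3 adjusted over the list alone), among them Fdps, farnesyl diphosphate synthase, which fell from 24180 ± 388 to 15980 ± 826 normalized counts. That list was lower (adjusted p = 1.14e-05, and adjusted p = 0.13 with an estimated correlation). Of 27 PPAR targets in fatty acid metabolism, 14 were higher and 7 lower (14 and 8 adjusted over the list alone), and the list was not called (adjusted p = 0.121). Acaa2, the thiolase that ends mitochondrial beta-oxidation, rose 2.73-fold, while Fabp4, a fatty acid binding protein, fell from 575.1 ± 52.9 to 27.07 ± 6.46, and Cpt1a, which admits fatty acids to mitochondria, fell from 2491 ± 7.31 to 1988 ± 22.8. Angptl4, an inhibitor of lipoprotein lipase, fell by 2.02 on the log2 scale. Among 10 LXR targets, 5 were higher and 1 lower, the same counts as adjusted over the list alone (adjusted p = 0.157), and Abcg1, a cholesterol exporter, rose 19.2-fold, from 76.47 ± 9.6 to 1470 ± 105. The LXR list was called higher in edgeR with genes of any count (adjusted p = 0.0438, the lowest of 20 other fits, which reached 0.258). Of 13 nuclear receptors and coregulators, 2 were higher and 7 lower, also adjusted over the list alone (adjusted p = 0.0729).

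Stress response genes were lower for 12 of 19 measured members and higher for 2 (12 and 3 adjusted over the list alone; adjusted p = 0.00152, and adjusted p = 0.169 with an estimated correlation). Trib3, a pseudokinase induced by the integrated stress response, fell from 14650 ± 758 to 3794 ± 528 normalized counts, and Ddit3, the transcription factor CHOP, fell from 13120 ± 183 to 4459 ± 51.3. Stress members numbered 7 higher and 12 lower under total count scaling. Hypoxia and glycolysis genes were higher for 13 of 24 and lower for 3, also adjusted over the list alone (adjusted p = 0.00481, and adjusted p = 0.284 with an estimated correlation). Egln3, a prolyl hydroxylase acting on hypoxia-inducible factor, rose 9.10-fold, from 307.7 ± 6.38 to 2802 ± 58.0, and Hk1, a hexokinase, rose 1.95-fold, while Slc2a1, a glucose transporter, fell from 65780 ± 3900 to 34750 ± 1940. Of 21 apoptosis genes, 12 were higher and 6 lower (13 and 6 adjusted over the list alone; adjusted p = 0.0493, and adjusted p = 0.28 with an estimated correlation). Pmaip1, the BH3 protein Noxa, rose from 533.9 ± 43.7 to 1544 ± 75.0, and Bcl2l1, the survival protein Bcl-xL, fell from 18080 ± 1180 to 8023 ± 634. The list joins genes that promote and genes that oppose cell death, so its call gives no direction of death. Bbc3, which promotes it, fell from 6557 ± 307 to 3133 ± 259, and Birc3, which opposes it, rose from 557.1 ± 12.7 to 1327 ± 36.8. The apoptosis call held in 8 of 20 other fits, whose adjusted p ran from 0.0347 to 0.11. It was lost under DESeq2 (adjusted p = 0.0819), total count scaling (0.104 with edgeR and 0.0963 with limma-trend) and edgeR on the 4 libraries compared (0.0545). It was also lost with genes of any count in edgeR (0.11) or limma-trend (0.0521) and with limma-trend on genes with a mean of at least 10 counts (0.0502), and over members with a mean of at least 50 (0.0623). Among left-out libraries, it was lost without untreated replicate 1 (adjusted p = 0.0544), without Dex replicate 2 (adjusted p = 0.0808), and without replicate 1 (adjusted p = 0.0549) or replicate 2 (adjusted p = 0.055) of Dex plus GW7647, whose libraries share the estimate of spread.

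Of 21 inflammatory and interferon genes, 4 were higher and 12 lower, also adjusted over the list alone, and the list missed the threshold (adjusted p = 0.0509). It passed without untreated replicate 1 (adjusted p = 0.0304) and without replicate 1 (adjusted p = 0.0446) or 2 (adjusted p = 0.0442) of Dex plus GW7647. It also passed under DESeq2 (0.00888), total count scaling (0.00795 with edgeR and 0.0102 with limma-trend), edgeR with genes of any count (0.00403) and edgeR on the 4 libraries compared (0.0429), and over 20 other fits the adjusted p reached 0.0855. Isg15, an interferon-induced ubiquitin-like protein, fell from 1390 ± 29.5 to 193.7 ± 2.12 normalized counts, and Ifit1, an interferon-induced RNA-binding protein, fell from 625.2 ± 90.5 to 46.28 ± 2.17, while Tnfaip3, an inhibitor of NF-κB signalling, rose 5.32-fold. Cytokine signalling and immediate early genes were higher for 10 and lower for 12 of 28 (10 and 13 adjusted over the list alone; adjusted p = 0.648). Jun, a subunit of the factor AP-1, fell from 3027 ± 41.4 to 809.9 ± 71.3, and Socs1, a suppressor of cytokine signalling, rose 3.96-fold. Ribosome biogenesis genes and MYC targets were higher for 2 and lower for 12 of 20 (3 and 12 adjusted over the list alone; adjusted p = 0.0625), with 6 higher and 6 lower under total count scaling, and the list was called lower without untreated replicate 2 (adjusted p = 0.0413).

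Markers of other blood cells moved as well. Megakaryocyte markers were lower for 11 of 13 measured members and higher for 0, also adjusted over the list alone (adjusted p = 1.89e-06, and adjusted p = 0.141 with an estimated correlation). Pf4, platelet factor 4, fell from 14970 ± 776 to 3808 ± 318 normalized counts. Granulocyte and eosinophil markers were lower for 12 of 16 and higher for 1, also adjusted over the list alone (adjusted p = 6.67e-05, and adjusted p = 0.169 with an estimated correlation). Mpo, myeloperoxidase, fell from 8200 ± 518 to 3463 ± 155. Mast cell and basophil markers went both ways, with 3 of 10 higher and 7 lower, also adjusted over the list alone (adjusted p = 0.121). Il1rl1, the interleukin 33 receptor, rose 7.37-fold, from 967.3 ± 23.8 to 7130 ± 342, and Hdc, the enzyme that makes histamine, rose 4.97-fold, while Cpa3, a mast cell carboxypeptidase, fell from 2876 ± 27.1 to 685.2 ± 54.6. Monocyte and macrophage markers were higher for 2 and lower for 5 of 8, also adjusted over the list alone (adjusted p = 0.0926), and Spi1, the myeloid transcription factor PU.1, rose 3.92-fold. Under total count scaling the mast cell and the monocyte list were both called lower (adjusted p = 0.0268 each with edgeR and 0.0349 each with limma-trend), while over 20 other fits the adjusted p reached 0.492 and 0.381. Lymphoid markers were lower for 2 of 4 (adjusted p = 0.231), hepatoblast markers higher for 2 of 4 (adjusted p = 0.185), and endothelial and stromal markers higher for 1 and lower for 1 of 4 (adjusted p = 0.732), with the same counts adjusted over each list alone.

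Among the largest differences, Ackr3, a scavenging receptor for the chemokine CXCL12, fell from 3013 ± 48 to 106.8 ± 20.1 normalized counts, and Sh3pxd2a, an adaptor protein of podosomes, fell from 253.5 ± 16.7 to 18.42 ± 3.13. Oxtr, the oxytocin receptor, fell from 141.6 ± 10.6 to 7.525 ± 1.36. Il1rl2, the interleukin 36 receptor, rose from 10.26 ± 7.97 to 555.3 ± 42.2, and Tnr, the matrix protein tenascin R, rose from 4.146 ± 0.677 to 248.6 ± 9.54. Trnp1, a nuclear protein, had 3 counts in untreated and 851 in Dex libraries, a ratio of 202 (95% counting interval 68.9 to 982), and Dnah2, a dynein heavy chain, had 1 and 330 counts, a ratio of 235 (41.9 to 9310).

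**Figure D1:**
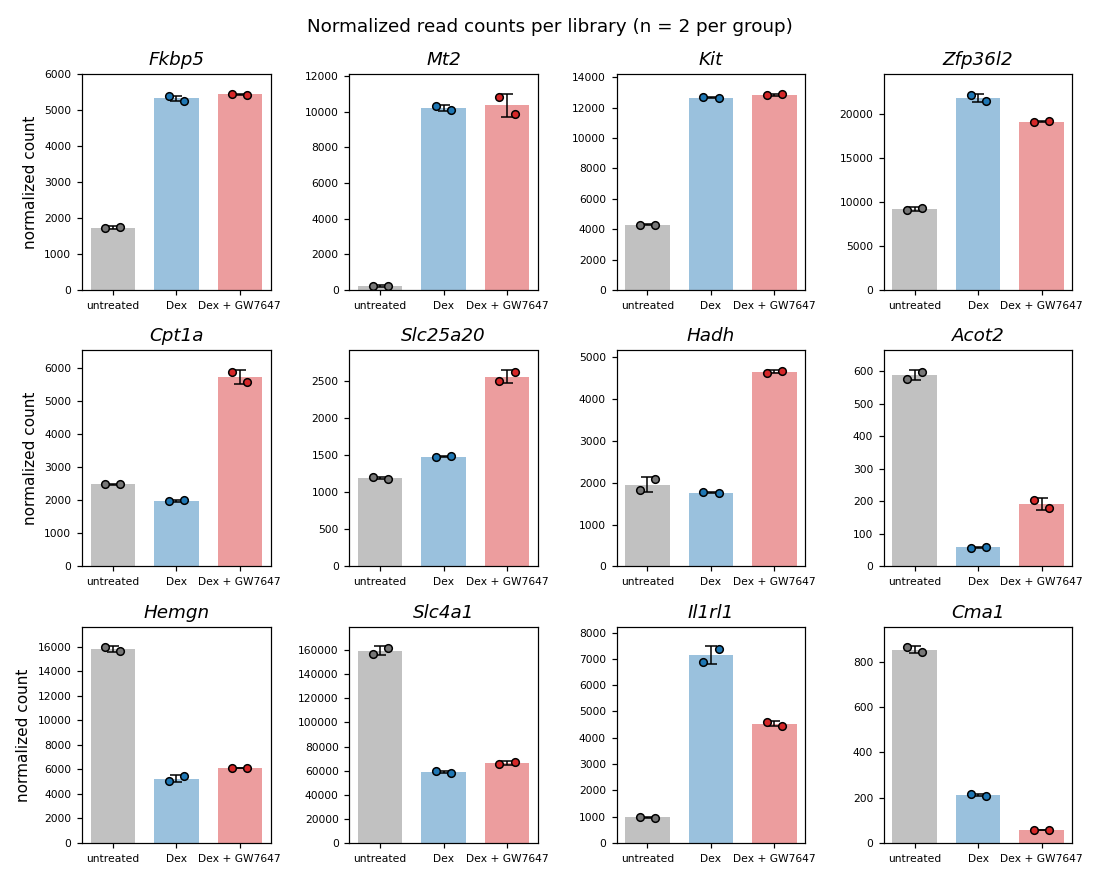
Normalized read counts of 12 genes, 1 panel per gene with its own vertical axis starting at 0. Bars are group means, points are the 2 libraries of each group and error bars are the SD. Kit stood at 12660 normalized counts with Dex and 12840 with both drugs, both above 4291 in untreated cells, whereas Cpt1a went from 1988 with Dex to 5742 with both drugs and Hadh from 1764 to 4655.

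With GW7647 added to Dex, 7 of 29 measured PPAR targets in fatty acid metabolism were higher, 0 were lower and 22 were not called, and the list was called higher (adjusted p = 0.0068, and adjusted p = 0.119 with an estimated correlation). That call was lost among matched random lists, where the list median stood at percentile 31.62. Markers were lower for 13 of 15 measured in granulocytes and eosinophils, 8 of 9 in mast cells and basophils and 9 of 12 in megakaryocytes. These lists were called lower, with an adjusted p = 0.0906, 0.0906 and 0.0956 with an estimated correlation. Cpt1a rose 2.89-fold, from 1988 ± 22.8 to 5742 ± 208 normalized counts (log2 1.53 ± 0.05, adjusted p = 2.13e-07). Hadh, a dehydrogenase of mitochondrial beta-oxidation, rose 2.64-fold, from 1764 ± 4.32 to 4655 ± 34.0 (adjusted p = 1.75e-06). Cma1, the mast cell chymase, fell from 211.3 ± 4.49 to 57.23 ± 0.761 (log2 -1.88 ± 0.12, adjusted p = 1.08e-05).

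The comparison asks what GW7647 adds to Dex. With edgeR, 1374 of the 14125 genes (9.73%) were called, 303 higher and 1071 lower with GW7647, and 16 and 201 of these differed at least 2-fold. The number of calls was 548 without replicate 1 of Dex plus GW7647 (64 higher and 484 lower), 618 without its replicate 2 (54 and 564) and 1729 without Dex replicate 2 (618 and 1111). The authors' deposited adjusted p values called 928 genes, 171 higher and 757 lower, and 918 of these were called here in the same direction.

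Adjusted over the list alone, 9 of the 29 PPAR targets in fatty acid metabolism were higher and 1 was lower. The median of -0.01 on the log2 scale had the opposite sign to its mean of 0.36 and its test. Besides Cpt1a, Slc25a20, the carnitine carrier of the inner mitochondrial membrane, rose 1.73-fold, from 1480 ± 12.9 to 2557 ± 86.1 normalized counts, and Acot2, a mitochondrial acyl-CoA thioesterase, rose 3.28-fold, from 58.47 ± 0.849 to 191.2 ± 18.1. Angptl4 stood at 140.7 ± 4.02 and 106.8 ± 12.4 (log2 -0.39 ± 0.13, adjusted p = 0.0877). Pdk4, a kinase that limits pyruvate oxidation, had between 2 and 9 counts per library and was not tested.

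Which receptor GW7647 acted through at the dose used cannot be told from the deposited counts. Ppara, which encodes PPARα, had 3 counts over all 6 libraries and was not tested. Ppard, which encodes the related receptor PPARδ, stood at 2031 ± 58.6 normalized counts with Dex and 1956 ± 15.9 with both drugs, a value chosen for this comparison after it was seen. Pparg, which encodes PPARγ, fell from 128 ± 3.36 to 36.98 ± 3.86 (log2 -1.78 ± 0.17, adjusted p = 0.00014). Nrip1, a corepressor of nuclear receptors, rose 1.29-fold. Of 13 nuclear receptors and coregulators, 1 was higher and 2 were lower (2 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.603, a test pointing up beside a median of 0.06 and a mean of -0.09).

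Other large rises were in Tcf23, a basic helix-loop-helix factor, from 14.45 ± 0.787 to 422.6 ± 5.34 normalized counts, in Abhd6, a monoacylglycerol hydrolase, from 24.09 ± 5.7 to 206.9 ± 34.8, in Slc7a3, a transporter of cationic amino acids, from 39.15 ± 2.98 to 150.7 ± 14.0, and in Gpt2, a mitochondrial alanine aminotransferase, from 143 ± 13.9 to 366.4 ± 22.9. Large falls were in Cd48, a ligand of the CD2 family on blood cells, from 659.1 ± 74.4 to 120.6 ± 6.87, in Gdf3, a TGF-beta family member, from 653.6 ± 43.7 to 163.3 ± 6.26, in Mmp14, a membrane metalloproteinase, from 120.4 ± 9.8 to 33.06 ± 3.35, and in Tcrg-C1, a T cell receptor gamma constant region, from 159.8 ± 8.78 to 46.53 ± 5.68.

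Markers of other blood cells were lower throughout the called members. Granulocyte and eosinophil markers were lower for 13 of 15 measured members (14 adjusted over the list alone; adjusted p = 1.02e-13, and adjusted p = 0.0906 with an estimated correlation). Elane, neutrophil elastase, fell from 326.4 ± 24.0 to 132.3 ± 8.36 normalized counts, and S100a8, a calcium-binding protein of neutrophils, fell from 853.7 ± 17.9 to 494 ± 2.92. Mast cell and basophil markers were lower for 8 of 9, also adjusted over the list alone (adjusted p = 9.39e-11, and adjusted p = 0.0906 with an estimated correlation). Tpsb2, a mast cell tryptase, fell from 153.8 ± 22.6 to 28.65 ± 5.44 and Il1rl1 from 7130 ± 342 to 4524 ± 96.4. Megakaryocyte markers were lower for 9 of 12 (10 adjusted over the list alone; adjusted p = 7.47e-08, and adjusted p = 0.0956 with an estimated correlation). Ppbp, pro-platelet basic protein, fell from 775.3 ± 139 to 288.6 ± 32.8 and Itga2b, the platelet integrin also known as CD41, from 8973 ± 765 to 5969 ± 5.62. Monocyte and macrophage markers were lower for 3 of 7 (6 adjusted over the list alone; adjusted p = 0.000103, and adjusted p = 0.0956 with an estimated correlation). Spi1 fell from 2595 ± 213 to 1407 ± 4.69 and Lyz2, a lysozyme, from 351.5 ± 14.8 to 206.2 ± 0.63.

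Markers of endothelial and stromal cells were lower for 2 of 4, also adjusted over the list alone (adjusted p = 0.00502, and adjusted p = 0.209 with an estimated correlation). Col1a2, a collagen chain, fell from 174.9 ± 16.7 to 73.23 ± 10.0 normalized counts. Without replicate 2 of Dex plus GW7647, 1 of the 4 was called. Hepatoblast markers were lower for 2 of 4 (3 adjusted over the list alone; adjusted p = 0.0314, and adjusted p = 0.265 with an estimated correlation). The hepatoblast call held in 11 of 20 other fits, whose adjusted p ran from 0.0118 to 0.178. It was lost without Dex replicate 1 (adjusted p = 0.0928), without replicate 2 of Dex plus GW7647 (0.0755), under DESeq2 (0.178), in edgeR with genes of any count (0.0618), in 5 limma-trend fits (0.0525 to 0.0678) and with scores from the authors' deposited p (0.111). Lymphoid markers were lower for 1 of 4 (2 adjusted over the list alone; adjusted p = 0.0615), and the list passed without replicate 2 of Dex plus GW7647 (adjusted p = 0.0391) and in 3 limma-trend fits (0.047 to 0.0494), while over 20 other fits the adjusted p reached 0.227.

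Glucocorticoid receptor targets were lower for 6 of 23 and higher for 0 (8 and 0 adjusted over the list alone; adjusted p = 0.00405, and adjusted p = 0.323 with an estimated correlation), and lower for 3 without replicate 1 of Dex plus GW7647. Zfp36, an mRNA decay factor, fell from 2253 ± 126 to 1539 ± 76.1 normalized counts, Dusp1, a MAP kinase phosphatase, fell from 701.9 ± 13.8 to 467.3 ± 18.9, and Cdkn1c, a cyclin-dependent kinase inhibitor, fell from 105.7 ± 7.63 to 44.9 ± 6.71. Fkbp5 stood at 5331 ± 81.2 and 5446 ± 15.5 (log2 0.03 ± 0.05, adjusted p = 0.732), and Nr3c1 at 2569 ± 157 and 2559 ± 58.3 (adjusted p = 0.972). Zfp36l2 fell by 0.19 on the log2 scale (adjusted p = 0.0255) and Tsc22d3 fell by 0.24 (adjusted p = 0.0214). Both calls were lost without Dex replicate 1 (adjusted p = 0.0719 and 0.0678) and without replicate 1 (0.213 and 0.14) or replicate 2 (0.209 and 0.209) of Dex plus GW7647. In the authors' deposited table, their adjusted p was 0.0543 and 0.0749.

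Kit stood at 12660 ± 36.9 with Dex and 12840 ± 64.4 with both drugs (adjusted p = 0.815), and Gata1 at 10440 ± 309 and 10360 ± 17.9 (adjusted p = 0.924). Of 34 erythroid differentiation genes, 2 were higher and 5 lower (4 and 7 adjusted over the list alone; adjusted p = 0.489). Hbb-y fell from 734.6 ± 58.9 to 335.8 ± 7.76 normalized counts and Aqp1, the red cell water channel, from 558.5 ± 33.6 to 208 ± 3.13. Heme synthesis and iron genes were higher for 3 and lower for 1 of 20, also adjusted over the list alone (adjusted p = 0.094). Early progenitor genes were higher for 1 and lower for 5 of 22 (1 and 6 adjusted over the list alone; adjusted p = 0.0131, and adjusted p = 0.209 with an estimated correlation). Hmga2, a chromatin protein of fetal progenitors, fell from 464.7 ± 19.4 to 282.7 ± 2.28. That list was not called without Dex replicate 2 (adjusted p = 0.076), and 2 and 3 members were lower without replicate 1 and replicate 2 of Dex plus GW7647.

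Cell cycle genes were called as a list with few called members. Of 32, 2 were higher and 0 lower (0 and 0 adjusted over the list alone), with a median of 0.10 on the log2 scale (adjusted p = 1.37e-05, and adjusted p = 0.0906 with an estimated correlation). Without Dex replicate 2, 8 members were higher, and without either library of Dex plus GW7647, 0 were. Kif11, a spindle motor, stood at 8329 ± 335 and 9373 ± 62.0 normalized counts (adjusted p = 0.0659). Cell cycle inhibitors were higher for 2 and lower for 6 of 16, also adjusted over the list alone (adjusted p = 0.0213, and adjusted p = 0.178 with an estimated correlation). Cdkn2b, the inhibitor p15, fell from 154.7 ± 15.9 to 70.29 ± 7.5. The inhibitor call was lost without Dex replicate 2 (adjusted p = 0.0959), without replicate 1 of Dex plus GW7647 (adjusted p = 0.0516) and in edgeR with genes of any count (adjusted p = 0.0631).

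Genes of cholesterol and lipid synthesis were higher for 8 of 31 and lower for 0 (10 and 1 adjusted over the list alone; adjusted p = 0.000445, and adjusted p = 0.0956 with an estimated correlation). That call was also lost among matched random lists (percentile 93.75). Scd1, the desaturase of stearoyl-CoA, rose from 5649 ± 171 to 7034 ± 149 normalized counts, and 1 member was higher without either library of Dex plus GW7647. Stress response genes were higher for 4 of 20 and lower for 0, also adjusted over the list alone (adjusted p = 0.00277, and adjusted p = 0.107 with an estimated correlation). Chac1, a glutathione-degrading enzyme, rose from 239.6 ± 18.0 to 370.8 ± 10.0, and 1 member was higher without either library of Dex plus GW7647. Apoptosis genes were lower for 5 of 21 and higher for 0, also adjusted over the list alone (adjusted p = 0.00309, and adjusted p = 0.107 with an estimated correlation), and lower for 2 without replicate 1 of Dex plus GW7647. Pmaip1 fell from 1544 ± 75.0 to 1075 ± 36.4.

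Inflammatory and interferon genes were higher for 1 and lower for 5 of 20 (1 and 7 adjusted over the list alone; adjusted p = 0.00434, and adjusted p = 0.209 with an estimated correlation), and lower for 3 without either library of Dex plus GW7647. Tnfaip3 fell from 812.1 ± 3.81 to 446.1 ± 15.6 normalized counts, Icam1, an adhesion molecule, from 230.5 ± 14.4 to 109.5 ± 11.1, and Relb, an NF-κB subunit, from 297.9 ± 5.61 to 188.3 ± 5.93. Hypoxia and glycolysis genes were higher for 3 and lower for 3 of 24 (4 and 3 adjusted over the list alone; adjusted p = 0.602). Vegfa, the endothelial growth factor, rose from 1105 ± 20.1 to 1431 ± 56.2 and Slc2a3, a glucose transporter, fell from 22040 ± 562 to 15110 ± 21.4. Cytokine signalling and immediate early genes were higher for 1 and lower for 1 of 28, also adjusted over the list alone (adjusted p = 0.418). Spry1, an inhibitor of receptor signalling, fell from 1289 ± 113 to 924.4 ± 22.8. LXR targets were lower for 1 of 10, also adjusted over the list alone (adjusted p = 0.864, a test pointing up beside a median of -0.06 and a mean of -0.04), the member being Abcg1. Among 20 genes of ribosome biogenesis and MYC targets, 0 were called, adjusted over the list alone as well (adjusted p = 0.0985).

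**Figure D2:**
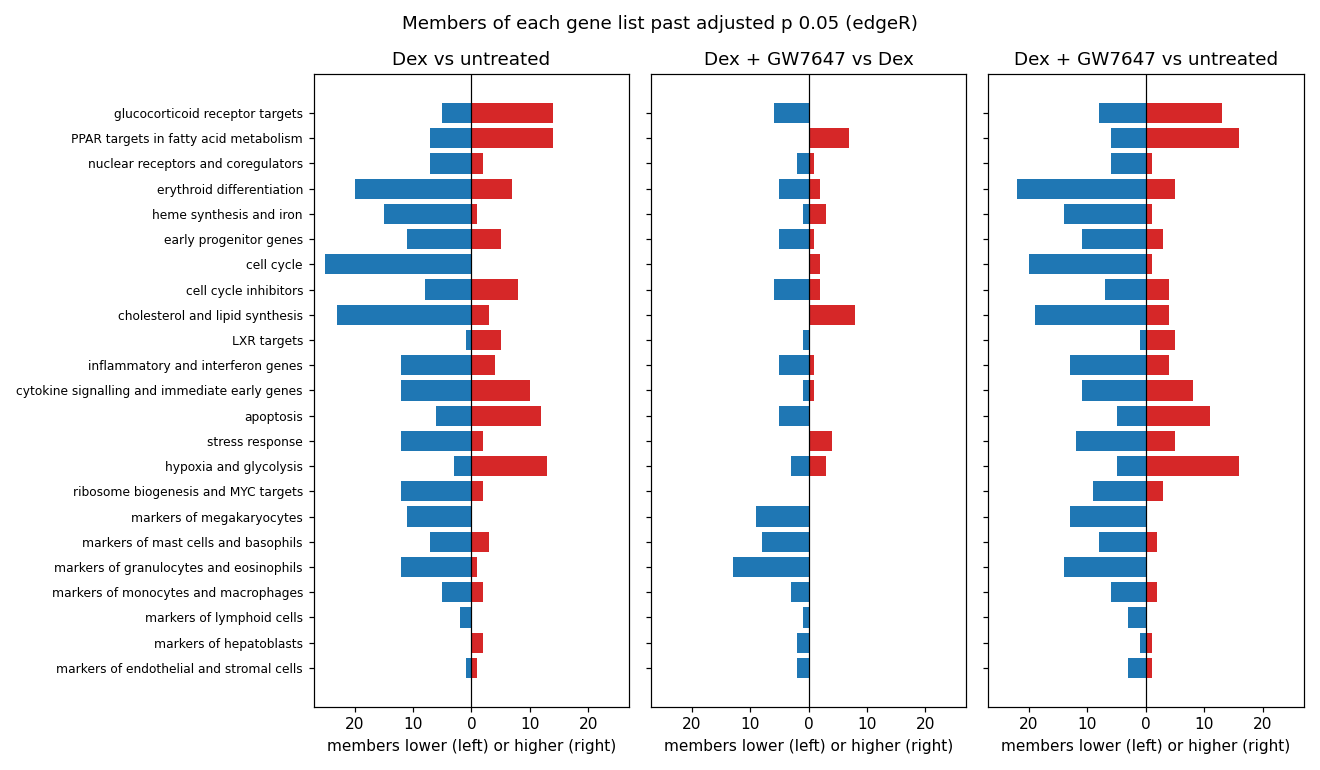
Number of members of each gene list called lower (bars to the left) or higher (bars to the right) by edgeR at an adjusted p under 0.05, 1 panel per comparison. With GW7647 added to Dex, 13 granulocyte markers, 9 megakaryocyte markers and 8 mast cell markers were lower and 0 of them were higher.

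With Dex plus GW7647 against untreated, 16 of 27 PPAR targets in fatty acid metabolism were higher and 6 lower, and 22 of 34 erythroid differentiation genes were lower and 5 higher. The PPAR list was called higher (adjusted p = 0.00681, and adjusted p = 0.151 with an estimated correlation) and the erythroid list lower (adjusted p = 5.04e-05, and adjusted p = 0.151 with an estimated correlation). Mt2 rose 44.6-fold, from 231.7 ± 33.7 to 10350 ± 651 normalized counts (log2 5.48 ± 0.09, adjusted p = 1.1e-09), and Fkbp5 rose 3.13-fold, to 5446 ± 15.5. Cpt1a rose 2.31-fold, from 2491 ± 7.31 to 5742 ± 208 (adjusted p = 4.26e-08). Kit rose 2.99-fold, to 12840 ± 64.4, and Slc4a1 fell from 159600 ± 3590 to 66430 ± 1590 (log2 -1.26 ± 0.04, adjusted p = 1.97e-08).

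The comparison asks how the cells with both drugs differ from untreated cells. With edgeR, 7025 genes (49.7%) were called, 3486 higher and 3539 lower, and 491 and 1280 of these differed at least 2-fold. Scaling by total counts, chosen after seeing the data, raised the median difference of all genes by 0.12 on the log2 scale and gave 8199 calls, 5480 higher and 2719 lower. The authors' deposited adjusted p values called 6055 genes, and 5975 of these were called here in the same direction.

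Of the 27 PPAR targets in fatty acid metabolism, 5 were not called, and 16 were higher and 6 lower adjusted over the list alone as well. Acaa2 rose 3.05-fold, from 3062 ± 166 to 9339 ± 197 normalized counts, while Fabp4 fell from 575.1 ± 52.9 to 43.62 ± 6.8 and Angptl4 from 569.5 ± 10.7 to 106.8 ± 12.4. Glucocorticoid receptor targets were higher for 13 and lower for 8 of 23, also adjusted over the list alone (adjusted p = 0.0819), with Ddit4 up 3.12-fold, Tsc22d3 up 2.15-fold and Zfp36l2 up 2.08-fold. That list was called higher under DESeq2 (adjusted p = 2.18e-06) and in edgeR with genes of any count (adjusted p = 9.76e-05), and over 20 other fits the adjusted p reached 0.252, so its call depends on the fit. Nr3c1 stood at 2775 ± 11.8 and 2559 ± 58.3 (adjusted p = 0.103), and was called lower without Dex replicate 2 (adjusted p = 0.0411). Of 13 nuclear receptors and coregulators, 1 was higher and 6 lower, also adjusted over the list alone (adjusted p = 0.0681), with 3 higher and 6 lower under total count scaling. Ppard fell from 2431 ± 33.7 to 1956 ± 15.9.

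Adjusted over the list alone, 6 of the 34 erythroid differentiation genes were higher and 23 lower, and under total count scaling the list median went from -0.281 to -0.162 on the log2 scale. Hemgn fell from 15790 ± 233 to 6085 ± 18.5 normalized counts and Hbb-y rose 8.17-fold. Gata1 fell by 0.20 on the log2 scale (adjusted p = 0.00773), a call lost without untreated replicate 2 (adjusted p = 0.0703), without replicate 1 (adjusted p = 0.059) or 2 (adjusted p = 0.064) of Dex plus GW7647, and under total count scaling (adjusted p = 0.19). Heme synthesis and iron genes were higher for 1 and lower for 14 of 20, also adjusted over the list alone (adjusted p = 0.000936, and adjusted p = 0.226 with an estimated correlation). Alas2 fell from 73750 ± 393 to 37460 ± 120 and Tfrc, the transferrin receptor CD71, from 105000 ± 4000 to 67760 ± 13.2, and under total count scaling 5 members were higher and 13 lower. Early progenitor genes were higher for 3 and lower for 11 of 23, also adjusted over the list alone (adjusted p = 0.0236, and adjusted p = 0.226 with an estimated correlation). Mycn, a MYC family factor, fell from 340.4 ± 5.93 to 57.16 ± 9.36. The median of that list was -0.118 on the log2 scale and 0.001 under total count scaling, with 6 higher and 11 lower. Its call was lost under DESeq2 (adjusted p = 0.0953) and among matched random lists (percentile 3.42), and held in the other 19 fits, from 0.0166.

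Cell cycle genes were higher for 1 and lower for 20 of 32, also adjusted over the list alone (adjusted p = 0.000936, and adjusted p = 0.151 with an estimated correlation). Birc5, survivin, fell from 7682 ± 171 to 5614 ± 325 normalized counts. Their lower members numbered 8 under total count scaling, and 12 and 11 without replicate 1 and replicate 2 of Dex plus GW7647. Cell cycle inhibitors were higher for 4 and lower for 7 of 16, also adjusted over the list alone (adjusted p = 0.115), and the list was called lower under DESeq2 (adjusted p = 0.0236, in a range up to 0.152). Ccng2, a cyclin of quiescent cells, fell from 4451 ± 35.7 to 2802 ± 10.9. Genes of cholesterol and lipid synthesis were higher for 4 and lower for 19 of 31, also adjusted over the list alone (adjusted p = 0.00493, and adjusted p = 0.151 with an estimated correlation). Fdps fell from 24180 ± 388 to 16140 ± 396. Under total count scaling, 7 were higher and 14 lower and the list median went from -0.168 to -0.048. That call was lost in edgeR with genes of any count (adjusted p = 0.0508) and held in the other 19 fits, from 0.00324. LXR targets were higher for 5 and lower for 1 of 10, also adjusted over the list alone (adjusted p = 0.107), and the higher members numbered 3 without untreated replicate 1 or without replicate 2 of Dex plus GW7647. The LXR list was called higher under DESeq2 (adjusted p = 0.0249) and in edgeR with genes of any count (adjusted p = 0.0164), in a range up to 0.18. Among its members, Abcg1 rose 14.0-fold.

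Inflammatory and interferon genes were higher for 4 and lower for 13 of 21, also adjusted over the list alone (adjusted p = 0.00555, and adjusted p = 0.179 with an estimated correlation). Isg15 fell from 1390 ± 29.5 to 141.6 ± 1.46 normalized counts and Oasl2, another interferon-induced gene, from 8964 ± 61.4 to 1878 ± 17.0. Stress response genes were higher for 5 and lower for 12 of 19, also adjusted over the list alone (adjusted p = 0.00681, and adjusted p = 0.151 with an estimated correlation). Ddit3 fell from 13120 ± 183 to 4443 ± 174 and Atf3, a stress-induced transcription factor, rose 2.85-fold. Hypoxia and glycolysis genes were higher for 16 and lower for 5 of 24 (16 and 6 adjusted over the list alone; adjusted p = 0.00668, and adjusted p = 0.226 with an estimated correlation). Egln3 rose 6.99-fold and P4ha1, a collagen prolyl hydroxylase, 1.79-fold. Apoptosis genes were higher for 11 and lower for 5 of 21, also adjusted over the list alone (adjusted p = 0.116). Bbc3, the BH3 protein Puma, fell from 6557 ± 307 to 2572 ± 92.5. Cytokine signalling and immediate early genes were higher for 8 and lower for 11 of 28 (10 and 11 adjusted over the list alone; adjusted p = 0.459). Pim1, a kinase induced by cytokines, fell from 24960 ± 811 to 11530 ± 511. Ribosome biogenesis genes and MYC targets were higher for 3 and lower for 9 of 20, also adjusted over the list alone (adjusted p = 0.115), and higher for 6 and lower for 4 under total count scaling.

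All 13 measured megakaryocyte markers were lower, also adjusted over the list alone (adjusted p = 6.63e-09, and adjusted p = 0.151 with an estimated correlation). Pf4 fell from 14970 ± 776 to 2606 ± 130 normalized counts. Granulocyte and eosinophil markers were lower for 14 of 16 (15 adjusted over the list alone; adjusted p = 6.63e-09, and adjusted p = 0.151 with an estimated correlation). Mpo fell from 8200 ± 518 to 2356 ± 4.7. Mast cell and basophil markers were higher for 2 and lower for 8 of 10, also adjusted over the list alone (adjusted p = 0.00668, and adjusted p = 0.151 with an estimated correlation). Cma1 fell from 853.6 ± 15.1 to 57.23 ± 0.761 and Il1rl1 rose 4.68-fold. The mast cell call was lost under DESeq2 (adjusted p = 0.0576) and held in the other 19 fits, from 0.000907. Monocyte and macrophage markers were higher for 2 and lower for 6 of 8, also adjusted over the list alone (adjusted p = 0.0236, and adjusted p = 0.2 with an estimated correlation). Spi1 rose 2.12-fold and Lyz2 fell from 1266 ± 57.4 to 206.2 ± 0.63. Lymphoid markers were lower for 3 of 4 (adjusted p = 0.0983), hepatoblast markers higher for 1 and lower for 1 of 4 (adjusted p = 0.502), and endothelial and stromal markers higher for 1 and lower for 3 of 4 (adjusted p = 0.269), with the same counts adjusted over each list alone. The lymphoid list was called lower under total count scaling with limma-trend (adjusted p = 0.0488) and, by a margin that rounding hides, with edgeR (adjusted p = 0.05), in a range up to 0.298.

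Among the largest differences, Adam33, a metalloproteinase, rose from 7.648 ± 3.9 to 229.9 ± 24.6 normalized counts. Trnp1 had 3 counts in untreated libraries and 373 with both drugs, a ratio of 107 (95% counting interval 36.3 to 521). Maob, monoamine oxidase B, fell from 181.5 ± 19.7 to 4.931 ± 1.96, Tpsg1, a mast cell tryptase, from 122.6 ± 22.9 to 6.251 ± 1.18, and Sfrp4, a secreted Wnt inhibitor, from 194.5 ± 20.9 to 11.01 ± 2.8.

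Genes called in both steps, Dex against untreated and then GW7647 added to Dex, were counted by direction. Here, moved back means that GW7647 changed a gene against its Dex direction, whether or not it ended nearer the untreated level. That held for 788 genes, 584 that Dex had raised and 204 that it had lowered. Independent lists would share 273 and 78.9. GW7647 moved 334 genes further in the Dex direction, 300 that Dex had lowered and 34 that it had raised. For these, independent lists would share 279 and 77.4. Some genes moved back passed the untreated level, and their number was not counted. Cpt1a stood at 2491 ± 7.31 normalized counts in untreated cells, 1988 ± 22.8 with Dex and 5742 ± 208 with both drugs. Gdf3 stood at 372.6 ± 2.06, 653.6 ± 43.7 and 163.3 ± 6.26. Il1rl1 went from 967.3 ± 23.8 to 7130 ± 342 normalized counts with Dex and back to 4524 ± 96.4, and Hbb-y from 40.85 ± 7.64 to 734.6 ± 58.9 and back to 335.8 ± 7.76. Prtn3, a protease of neutrophil granules, fell at both steps, from 1900 ± 204 to 890 ± 33.4 and 503.7 ± 14.2. Both steps share the Dex libraries, whose noise alone favours genes moved back. In 20 simulations of unchanged groups, the mean number moved back was 1.15 and the mean number moved further was 0, which is chance with no effect in either step and not the share of that noise among called genes. When separate Dex libraries served the 2 steps, 589 genes moved back and 264 further with replicate 1 in the step from untreated, and 768 and 381 with replicate 2.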

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

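The alternatives with edgeR under total count scaling, with genes of any count, with robust dispersions, on the 4 libraries compared, with a crossed block or with thinned libraries, the list tests under other fits, and the overlap under DESeq2 or total count scaling were chosen only after the results were seen. Counting only genes that differed at least 2-fold left 1771 calls for Dex plus GW7647 against untreated, 217 for Dex plus GW7647 against Dex, and 1718 for Dex against untreated, since that setting keeps part of the called genes. For Dex plus GW7647 against Dex, with 1374 calls, an adjusted p threshold of 0.1 gave 2105 and a threshold of 0.01 gave 676. Keeping genes with any count gave 2085 for that comparison with edgeR (578 higher and 1507 lower) and 1080 with limma-trend (194 and 886), and the cause was not tested. With single libraries left out, its counts ran from 548 (without replicate 1 of Dex plus GW7647) to 1729 (without Dex replicate 2), with 618 without replicate 2 of Dex plus GW7647, and fewer libraries stood behind each of these fits. The counts ran from 5285 to 7646 for Dex plus GW7647 against untreated and from 6067 to 7077 for Dex against untreated. Apart from these and the crossed block below, total counts of genes were within 1.5 times those reported, and for Dex plus GW7647 against Dex they ran from 928 with the authors' p to 1565 with robust dispersions where no library was left out. The 303 higher calls of that comparison became 171 with the authors' p, 194 with limma-trend on genes of any count, 64 and 54 without replicate 1 and replicate 2 of Dex plus GW7647, and 618 without Dex replicate 2. Under total count scaling the higher calls went from 3606 to 5451 for Dex and from 3486 to 5480 for both drugs, each against untreated. Called lists numbered 13 of 23 for Dex plus GW7647 against untreated, 15 for Dex plus GW7647 against Dex and 10 for Dex against untreated. Camera with an estimated correlation called 0 in each, a test with little power at 2 libraries per group. Over members with a mean of at least 50 the numbers were 14, 14 and 9. Among matched random lists they were 16, 15 and 15, but for partly different lists: PPAR targets and cholesterol synthesis for Dex plus GW7647 against Dex and early progenitor genes for both drugs against untreated were not called. That test added, for both drugs against untreated, glucocorticoid receptor targets, nuclear receptors, apoptosis and lymphoid markers, and against Dex, hypoxia genes and lymphoid markers. For Dex against untreated it added PPAR targets, inflammatory genes and markers of mast cells, monocytes and hepatoblasts. Scores from the authors' deposited p gave 16 lists for both drugs against untreated, adding glucocorticoid receptor targets (adjusted p = 3.43e-05), cell cycle inhibitors (0.0279) and LXR targets (0.0137), and 14 against Dex. With single libraries left out these numbers were 13, 13 to 15, and 9 to 11. Genes moved further by GW7647 numbered 537 at an adjusted p under 0.1 in both steps. Of the results for single named genes, 0 reversed under any of these settings, while 33 of 322 were no longer called without replicate 1 of Dex plus GW7647 and 30 without its replicate 2. Most of these losses were in Dex plus GW7647 against Dex, where 83 named genes had been called, so their share is larger there. On simulated counts with 200 of 14125 genes changed, 64% to 78% of 1.5-fold changes were recovered at the depth and spread of these libraries.

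The labels give no shared source for libraries with the same replicate number. The deviations of such libraries from their group means correlated at -0.05 for Dex plus GW7647 against untreated, 0.15 for Dex plus GW7647 against Dex and -0.21 for Dex against untreated, and 2 libraries per group are too few to show a pairing. A block for the replicate number changed the counts to 6523 for Dex plus GW7647 against untreated, 998 for Dex plus GW7647 against Dex (154 higher and 844 lower) and 6824 for Dex against untreated. With the block, the apoptosis list for Dex against untreated was not called (adjusted p = 0.0512) and the lymphoid list for Dex plus GW7647 against Dex was (0.0414). Of the 322 results for single named genes, 10 were no longer called, among them Zfp36l2 (0.0637) and Tsc22d3 (0.0563) for Dex plus GW7647 against Dex. A crossed block, with the numbers of the untreated libraries exchanged, gave 7791, 2240 (731 higher and 1509 lower) and 8044 genes, and the cause of the difference was not tested.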

Other observations

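The tests of a smaller share of other cells, of total count scaling for the red cell genes, of an earlier stage and of shared library noise were chosen only after the result was seen. The genes in the next paragraph were also chosen after their values were seen, and their calls held with each library left out and under total count scaling.

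Further list members moved with, against or apart from the rest of their list. Rhag, a membrane protein of the Rh complex of red cells, rose with Dex (log2 0.59 ± 0.05, adjusted p = 9.13e-06) and Epor, the erythropoietin receptor, stood at 7341 ± 582 and 7456 ± 704 normalized counts (adjusted p = 0.813). Bcl6, a transcriptional repressor on the list of glucocorticoid receptor targets, fell by 2.69 with Dex, while Mt1, a metallothionein, rose by 1.74 ± 0.09 and Per1, a clock gene, by 1.19 ± 0.06. With GW7647 added to Dex, Etfdh, which passes electrons from beta-oxidation to the respiratory chain, rose from 4022 ± 209 to 5432 ± 21.0, and Plin2, a coat protein of lipid droplets, from 6663 ± 126 to 8307 ± 93.4. Acadl, the long-chain acyl-CoA dehydrogenase, rose from 3435 ± 247 to 6897 ± 388 with Dex and stood at 6533 ± 62.5 with both drugs (adjusted p = 0.47 against Dex). Among the markers of granulocytes, Ngp, a neutrophil granule protein, fell from 90.69 ± 1.68 to 33.82 ± 0.604 with GW7647 added, and among those of mast cells, Ms4a2, a chain of the IgE receptor, fell from 145.6 ± 6.23 to 63.55 ± 9.7.

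With GW7647 added to Dex, 33 of 43 measured markers of megakaryocytes, mast cells, granulocytes and monocytes were lower, and the most abundant were Itga2b at 8973 ± 765 and 5969 ± 5.62, Hdc at 8683 ± 277 and 5030 ± 64.6, and Il1rl1 at 7130 ± 342 and 4524 ± 96.4 normalized counts. A difference in depth is argued against, because 32 of these 33 stayed lower in libraries thinned to the smallest total. A smaller share of such cells in the cultures stays open, since 0 of the 43 were higher, a count that lower expression within the progenitors would give as well and that was known when the test was chosen. The sort had removed cells with lineage markers, CD16/32 and CD41, the last encoded by Itga2b. It came before the treatment, so it cannot decide on cells that arose later. Untreated libraries also held such transcripts, with Itga2b at 9722 ± 203 and Mpo at 8200 ± 518 normalized counts. An equal loss of all markers of a type, with no part from other cells, is argued against for megakaryocytes, within the spread between these libraries. Their markers fell by unequal amounts relative to that spread. It may be technical, so falls made unequal by variation between cultures are not excluded. Cochran's Q per degree of freedom was 14.4 for the megakaryocyte list. It was 7.9 for monocyte and macrophage, 4.7 for granulocyte and eosinophil and 24.7 for mast cell and basophil markers. Those lists join cell types, so their unequal falls do not decide it per type. Markers made partly by the progenitors would also fall unequally, so a loss of cells itself is not excluded.

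With Dex, 20 of 34 erythroid genes were lower, and globin transcripts took a smaller part of the counts. Scaling is argued against as the whole cause, because 16 of the 20 stayed lower under total count scaling, but it bears on the size, since the list median went from -0.224 to -0.094 and the higher members from 7 to 8. A loss of carried-over red cell RNA that holds little but globin is argued against too, since 17 of the 29 erythroid genes left without globins were lower, and that list was still called (adjusted p = 0.00077, and adjusted p = 0.18 with an estimated correlation). Cells held at an earlier stage could give this pattern, but the early progenitor list was not called (adjusted p = 0.209, 5 higher and 11 lower), so the test leaves it open. Whether untreated cells were cultured is not stated, so a difference in culture between the groups also stays open.

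GW7647 moved 788 genes back, against their Dex direction, and 334 further along it. Genes moved back need not end nearer the untreated level, and Cpt1a and Gdf3 passed it. Noise of the Dex libraries that both steps share is argued against as the whole cause, because with separate Dex libraries the genes moved back were still 1.96 and 2.22 times the number for independent lists. The covariance of the 2 steps with shared libraries was -0.0384, against -0.0166 in 20 simulations of unchanged groups, and with separate libraries it was -0.022 and -0.013, against -0.000215 and -0.000338. Separate libraries remove only noise that differs between the 2 Dex libraries. Whether these came from separate cultures is not stated, so a deviation common to both Dex libraries stays open. A weakening of every Dex rise by the same fraction on the log2 scale is argued against, within the spread between these libraries. Around a slope of -0.16 for the 230 genes that Dex raised at least 4-fold, Q per degree of freedom was 16.5. Of these genes, 101 were lower, 0 higher and 129 not called with GW7647 added. A general weakening by unequal fractions could give such counts too, so it stays open. An action of GW7647 on part of the Dex-raised genes may remain as a hypothesis, and without a group given GW7647 alone it was not tested.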
